A study of Homo sapiens with 30 samples.

How the data were processed

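Poly(A) RNA from 30 libraries labelled A549, 15 groups of 2, had been extracted with TRIzol, made into libraries with a VAHTS Universal V6 kit and read from both ends at 150 bp, per the labels' protocols, which also state that 10% of fly S2 cells were added. The deposited counts are whole numbers of reads per gene, which the authors made with Trim Galore 0.6.2, STAR 2.7.3a and featureCounts 2.0.1 on builds hg38 and dm6, per the submitters' processing notes. The annotation release, the strand setting and the treatment of reads that fit several genes are not given in the sources used here. The deposited TPM values, made by the authors, summed to 998366 to 999347 per library and equalled the counts over 1 length per gene, rescaled per library (relative spread 0.0%), so they served only as a check. For each of the 7 treated lines the authors' deposited table gives a base mean (a signal: mean count over a factor per library), a log2 fold change and a p-value with its adjusted form, made with DESeq2 1.24.0 per the submitters' processing notes. Its factors were solved from the base means of the listed genes found in the count tables (29112 to 31625 a line) and gave these back exactly.

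All 61578 genes of the count tables are human; 0 fly genes are listed, so the fly scaling planned as the first choice could not be made and TMM, the choice fixed for that case, was used. Of the gene IDs, 56659 matched GENCODE release 29, from which coordinates, transcript length and GC content were taken, and 4919 did not; 20565 had no symbol. Library totals were 10866089 to 17912802 counts. A group at 0 counts was given the limit that a count of 0 allows, 3 counts over its 2 libraries; floors and counting intervals (exact, 95%) cover counting error only.

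Counts were tested with edgeR 4.0.16 (quasi-likelihood, robust) in R 4.3.3, with TMM factors and 1 coefficient per group over all 30 libraries, which left 15 residual degrees of freedom (common dispersion 0.0122). Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 19982 tested and 41596 not. Benjamini-Hochberg adjustment ran within each comparison, and an adjusted p under 0.05 was a call. Standard errors are the log2 fold change over the square root of its F statistic. The 20 comparisons were treated against untreated in 7 lines, the difference in change of WT against the degron line and of each mutant against WT (6 comparisons), and untreated lines against Mock or against the untreated degron line (7 comparisons). "Risen" and "fallen" mean called upward and downward; CPM values use TMM-scaled library sizes.

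The 26 gene lists and the 4 lists of markers of other cells were fixed before the data were examined, as were all tests, the rule for named genes and all alternatives but those said to be chosen later. Each list was tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated one, adjusted over the lists of a comparison with at least 3 tested members. Camera's adjusted p is the former unless an estimated correlation is named. Where list members were at 0 in a group, the median is given again with those members at their bound. Named genes were, per line, up to 10 risen and 10 fallen with the largest fold change among called genes with a mean of at least 5 CPM and both treated libraries beyond both untreated ones; up to 5 each way per other comparison, where for a difference in change all 4 treated minus untreated differences of one line lay beyond all 4 of the other; POLR2A; and up to 4 members per list. Clone-type names, IDs without symbol and pseudogenes were left out by that rule, and the text prints part of the genes it gives; 1 gene is not reported here. Genes whose call depended on 1 library are given with that library or left out.

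Genes with near-identical copies or overlapping neighbours are uncertain, since reads can be split between them: histone genes, HSPA6, MGAM and MGAM2, FUT3 and FUT6, the AKR1C genes and the HSPA1 genes. So are genes with an antisense or host partner, such as FOXCUT, FENDRR, LINC01605, LINC01963 and the small nucleolar RNA host genes, because the strand setting of the counting is not given. No replicate pair was counted as 1 library: the chi-square of counts per degree of freedom between the 2 libraries of a group was 1.26 to 24.7.

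Alternatives were DESeq2 1.42.0 size factors and its Wald test, scaling by 13 mitochondrial mRNAs, no low-count filter, a mean CPM of at least 5, a replicate block, each line's own 4 libraries, treated libraries compared directly, and each library left out. Added after the data were seen were GC correction (a spline of each library's deviation against transcript GC content as an offset, over genes with a mean of at least 1 CPM), also with the block, the authors' factors and a fit without the 2 Mock libraries. The test was checked on simulated counts with 200 changed genes. Tables and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.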

Results

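Poly(A) RNA was sequenced from 30 libraries labelled as the human lung adenocarcinoma line A549, in 15 groups of 2. RPB1, encoded by POLR2A, is the largest subunit of RNA polymerase II, and its C-terminal domain (CTD) repeats a heptad whose residues are phosphorylated during transcription. In the degron line the endogenous RPB1 could be degraded with dTAGV-1, and 6 further lines also carried a doxycycline-induced RPB1 whose CTD was wild type (WT) or had tyrosine 1 changed to phenylalanine (Y1F), serine 2 to alanine (S2A), threonine 4 to valine (T4V), serine 5 to alanine (S5A) or serine 7 to alanine (S7A). Each line was sampled untreated and treated: 2 µg/mL doxycycline for 24 h with 100 nM dTAGV-1 for 12 h, or dTAGV-1 alone in the degron line, so that the WT and degron lines also differ in doxycycline. The 15th group, Mock, was untreated and labelled wild type in genotype. The question was how gene expression changed when each CTD mutant replaced the endogenous protein. Nothing in the labels says the 2 libraries of a group were separate cultures, so p-values measure only spread between libraries, which may be technical. Spread was pooled over the 15 groups, so call counts are not comparable between lines. With its own 4 libraries WT went from 985 to 50 calls and S5A from 9928 to 12388. Values below are log2 fold changes±standard error from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, n = 2 libraries per group, and levels are means in counts-per-million (CPM).

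POLR2A mRNA (chromosome 17, 7484366 to 7514616, plus strand), from which both the endogenous and the induced protein are made, was counted first. It stood at 439±47.2 CPM (SD, n = 2) in Mock. With treatment it went from 569.9±3.54 to 1572±272 CPM in the S7A line, from 391±28.8 to 1052±53 CPM in S5A, from 296±8.91 to 769±355 CPM in WT, from 296±0.919 to 639±57.6 CPM in S2A and from 327±53.9 to 640.0±48.8 CPM in Y1F. It rose in these 5 lines, by 1.46±0.27, 1.43±0.27, 1.38±0.27, 1.11±0.27 and 0.97±0.26 on the log2 scale (adjusted p = 2.3e-04, 1.4e-04, 0.0034, 0.0025 and 0.0052, edgeR's test). In the T4V line it went from 356±111 to 526±12.1 CPM (0.56±0.26, adjusted p = 0.11 in edgeR's test) and in the degron line, which has no induced copy, from 374±122 to 549.9±197 CPM (0.55±0.26, adjusted p = 0.092), neither of which passed. With edgeR's test and 1 library left out, the value was 1.35 without untreated WT replicate 2 (adjusted p = 0.059), 0.81 without treated WT replicate 2 (adjusted p = 0.12), 0.77 without untreated Y1F replicate 2 (adjusted p = 0.067), 0.92 without untreated degron replicate 1 (adjusted p = 0.029) and 0.80 without treated degron replicate 1 (adjusted p = 0.025). With the authors' factors described next it was -0.31 in the degron line, 1.23 in WT, 0.09 in Y1F, 0.59 in S2A, 0.12 in T4V, 0.47 in S5A and 0.63 in S7A. With mitochondrial scaling it was -0.03 in T4V. In edgeR's test no mutant line differed from WT in the change of POLR2A, nor did WT from the degron line (adjusted p = 0.16 to 0.97). Reads of the endogenous and induced transcripts were not told apart, and the protein was not measured here.

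**Figure D1:**
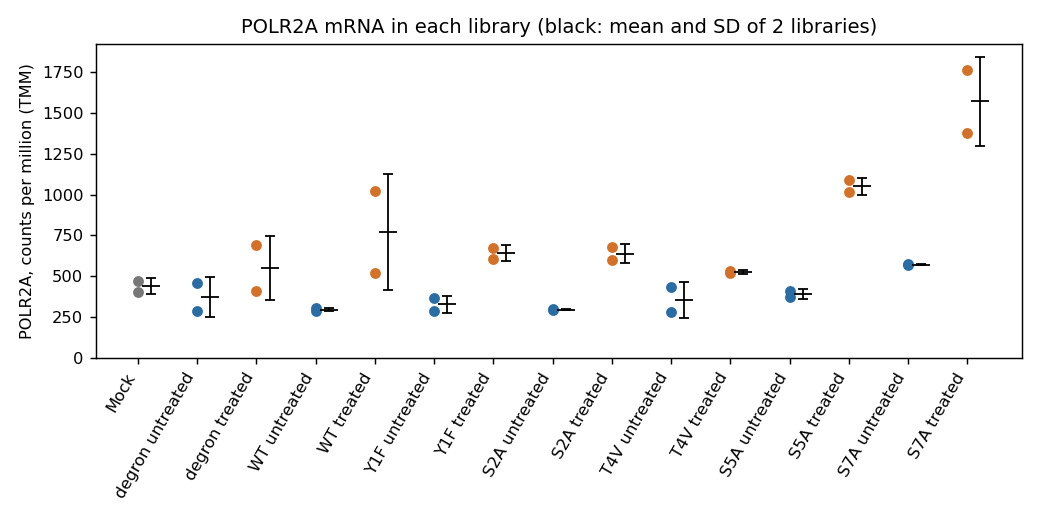
POLR2A level in counts-per-million (vertical axis) for each of the 15 groups (horizontal axis), with points for the 2 libraries and a black mark with error bars for their mean and SD. The mean was 1572 CPM in treated S7A and 296 CPM in untreated WT.

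Scaling by TMM sets the typical gene to no change, so a change of all mRNAs together cannot be seen in it. The authors' deposited table of each line gave 10790 genes called in the degron line (552 higher and 10238 lower), 21 in WT (15 higher and 6 lower) and 11199 in Y1F (619 higher and 10580 lower), at an adjusted p under 0.05. The authors' deposited table gave 9067 in S2A (677 higher and 8390 lower), 5382 in T4V (231 higher and 5151 lower), 12835 in S5A (977 higher and 11858 lower) and 10198 in S7A (475 higher and 9723 lower). Set against the TMM values of the same genes, the log2 fold changes of the authors' deposited table were shifted by a median of -0.86 in the degron line, -0.23 in WT, -0.88 in Y1F, -0.52 in S2A, -0.46 in T4V, -0.96 in S5A and -0.82 in S7A. The factor of each library could be solved from the base means of the authors' deposited table, and total counts over that factor in the treated libraries came to 56.4% in the degron line, 84.3% in WT, 51.2% in Y1F, 71.5% in S2A, 75.4% in T4V, 49.7% in S5A and 56.1% in S7A of the untreated ones, as means of 2 libraries whose ranges overlap in WT. Below these are the authors' factors, mitochondrial scaling is that by the 13 mRNAs of the mitochondrial genome, and each, or both scalings together, is named where it turned the median of a list given as called by camera. Direction in the text is relative to the typical gene unless another scaling is named. Where a list's count moved by over 1.5 times, "scaled" gives its members risen and fallen with mitochondrial scaling, then with the authors' factors. Within a line, camera's upward calls were each lost with at least 1 of these scalings, except for the histone genes, the short-lived mRNAs in S2A, the ATF4 targets in WT, the mitochondrial mRNAs in T4V and markers given below. Its downward calls lost, beside markers, were the NF-kB targets in degron and, with GC correction, the splicing factors in WT and S7A.

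**Figure D2:**
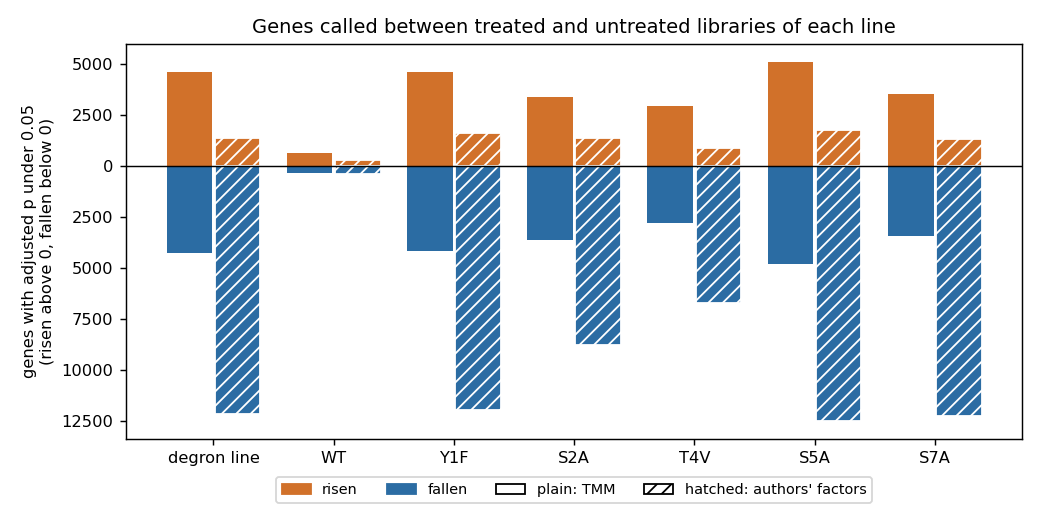
Number of genes (vertical axis) called as risen (above 0) and fallen (below 0) between treated and untreated libraries of each of the 7 lines, 2 libraries per group, with TMM (plain bars) and with the authors' factors (hatched bars). In the degron line 4609 genes rose and 4272 fell with TMM, and 1384 rose and 12159 fell with the authors' factors.

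Degradation of RPB1 without replacement was followed by lower levels of several regulatory transcripts. MYC, the growth-promoting transcription factor, fell from 519 to 23.1 CPM (-4.49±0.15), and IRS4, an insulin receptor substrate, from 1420.0 to 161 CPM (-3.14±0.12). HES5, a Notch target, fell by the most of the named genes (-5.58±0.38), with SMAD6, an inhibitor of BMP signalling (-4.03±0.18), NOG, which encodes the BMP antagonist noggin (-3.73±0.27), LRATD2 (-3.60±0.12), the potassium channel subunit KCNJ11 (-3.50±0.35), the acetyltransferase KAT5 (-3.14±0.23) and ZBTB22 (-3.07±0.27). Among genes near 0 before treatment, those higher after it were TG, the thyroid hormone precursor (at least 108-fold, 0 counts in the untreated libraries), MGAM2 (ratio 538, 96.3 to 21300.0 as 95% counting interval), its neighbour the maltase-glucoamylase MGAM (4.70±0.25), the myelin protein MOBP (5.76±0.33), C1orf116 (4.80±0.28), ELAPOR1 (4.73±0.20), the epidermal protein SBSN (4.63±0.40), the P-selectin ligand SELPLG (4.54±0.41), the retinal receptor GPR179 (4.03±0.26) and ADGRF3 (4.02±0.26). A group at 0 gives a lower bound against 3 counts over its 2 libraries. One with 1 to 3 counts gives a ratio with counting interval. In edgeR's test, these genes had adjusted p from 5.9e-15 to 7.3e-08, and 8881 of 19982 genes tested were called, 4609 risen and 4272 fallen, of which 2453 and 1642 by at least 2-fold. The count was 10441 with mitochondrial scaling (1942 higher and 8499 lower, median -0.42) and 13543 with the authors' factors (1384 higher and 12159 lower, median -0.79).

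Most mRNAs of replication-dependent histone genes lack a poly(A) tail and so go uncounted here. Of these genes, 22 of 32 rose and 0 fell (the same adjusted over the list alone, scaled 15 and 0, 12 and 3). H2BC6 was higher (ratio 80.3, 14.1 to 3200.0 as counting interval, from 1 count). The median was 1.70, with camera adjusted p = 1.1e-05 (0.001 with an estimated correlation). Genes under 1 CPM untreated had a median of 0.95, and genes of like level were not compared. Of immediate early and other short-lived mRNAs, 5 of 35 rose and 16 fell (the same over the list alone; scaled 0 and 25, 0 and 30), with the BMP-responsive ID3 at -2.79±0.18. The median was -0.62, with camera adjusted p = 3.9e-04, adjusted p = 0.22 with an estimated correlation. Of the small nucleolar RNA (snoRNA) host genes, 1 of 18 rose and 11 fell (1 and 12 over the list alone), with SNHG3 at -2.07±0.12 and SNHG15 at -1.82±0.14. The median was -0.73, with camera adjusted p = 1.5e-04, adjusted p = 0.083 with an estimated correlation. Of the mRNAs of the mitochondrial genome, which another polymerase transcribes, 12 of 13 rose and 0 fell (the same over the list alone; scaled 2 and 0, 0 and 5). The median was 0.49, with camera adjusted p = 3.4e-04, adjusted p = 0.27 with an estimated correlation. The median was 0.00 with mitochondrial scaling, which holds these mRNAs near no change by construction, and -0.37 with the authors' factors. Of the nuclear-encoded respiratory chain genes, 17 of 37 rose and 0 fell (18 and 0 over the list alone; scaled 0 and 4, 0 and 26). The median was 0.35, with camera adjusted p = 8.9e-04, adjusted p = 0.35 with an estimated correlation. The median was -0.13 with mitochondrial scaling and -0.51 with the authors' factors. The number risen was 8 without untreated degron replicate 2, and 7 without treated degron replicate 2. H2BC6, ID3, SNHG3 and SNHG15 passed edgeR's test (adjusted p from 3.1e-11 to 1.5e-08).

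Camera called 8 more lists downward, given with members risen and fallen over all genes, which were the same over the list alone: the HIF target genes (1 and 12 of 20, median -0.35, adjusted p = 0.013), the BCL2 family (1 and 9 of 15, median -0.54, adjusted p = 0.0073) and the Integrator subunits (0 and 6 of 14, median -0.31, adjusted p = 0.031), with adjusted p = 0.083 to 0.15 with an estimated correlation. The other lists were the DNA damage response genes sensitive to CDK12 loss (0 and 9 of 18, median -0.37, adjusted p = 0.02), the SR and hnRNP splicing factors (3 and 11 of 26, median -0.27, adjusted p = 0.013), the NF-kB target genes (0 and 5 of 14, median -1.20, adjusted p = 0.042), the ATF4 and integrated stress response targets (1 and 10 of 24, median -0.18, adjusted p = 0.044) and the G2 and mitosis genes (3 and 10 of 28, median -0.12, adjusted p = 0.02), with adjusted p = 0.29 to 0.35 with an estimated correlation. In the order given, 15, 11, 11, 14, 22, 7, 17 and 23 fell with mitochondrial scaling and 17, 14, 13, 18, 24, 9, 22 and 26 with the authors' factors. Adrenomedullin (ADM), a HIF target, stood at -1.19±0.16, VEGFA at -1.02±0.16, the apoptosis activator HRK at -1.92±0.21, RAD51D, a DNA repair gene, at -1.61±0.13 and SRSF3, a splicing factor, at -1.57±0.10. The number fallen was 5 without treated degron replicate 2 for the DNA damage response genes, 7 without treated degron replicate 2 for the splicing factors and 6 without untreated degron replicate 1 for the ATF4 targets, and the call of the NF-kB targets (median -1.60 with members near the floor left out) was lost with mitochondrial scaling (adjusted p = 0.26), GC correction (adjusted p = 0.083) and the authors' factors (adjusted p = 0.37). The single genes named with these lists passed edgeR's test (adjusted p from 8.2e-11 to 2.1e-05).

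Camera called none of the remaining lists in the degron line. In parentheses stand their genes risen and fallen over all genes tested, then over the list alone where this differs, and the number tested: the fibroblast markers (0 and 1 of 3), the endothelial markers (2 and 0 of 4), the other RNAPII subunits (4 and 0 of 11), the CTD kinases and phosphatases (3 and 8 of 23), the RNAPII elongation factors (6 and 7, 7 and 7 alone, of 26), the cleavage, polyadenylation and termination factors (5 and 7 of 20), the p53 target genes (8 and 7 of 28), the heat shock and chaperone genes (4 and 5 of 18), the interferon-stimulated genes (6 and 1 of 22), the NRF2 target genes (7 and 2, 6 and 2 alone, of 28), the DNA replication and S phase genes (4 and 11 of 31), the cytosolic ribosomal protein genes (6 and 2, 1 and 2 alone, of 78), the cholesterol synthesis genes (4 and 5 of 22) and the A549 and lung epithelial genes (3 and 3 of 16). With the authors' factors more fell than rose in each of these lists but the endothelial markers, such as 0 risen and 73 fallen of the ribosomal protein genes (0 and 23 with mitochondrial scaling), 0 and 6 of the RNAPII subunits (0 and 2), 2 and 15 of the NRF2 targets (2 and 7), 1 and 10 of the interferon-stimulated genes (3 and 5) and 1 and 17 of the p53 targets (2 and 11). Of the small nuclear RNA genes only 2 could be tested, too few for camera, and 1 rose and 0 fell. The immune markers had a median of 3.42 (2 risen and 0 fallen of 3, camera adjusted p = 0.027) and the kidney HEK293 or neuronal markers one of -0.97 (0 risen and 2 fallen of 4, camera adjusted p = 0.013), with adjusted p = 0.15 with an estimated correlation. Here and in the lines below, each call of such markers was lost with GC correction or a scaling (adjusted p = 0.054 to 0.21), except those of the immune markers in S5A and S7A.

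Replacement by the wild-type CTD was the control for each mutant. HSPA6, a strictly stress-inducible HSP70, rose from 0.359 to 35.0 CPM (6.56±0.32), with the cystine transporter SLC7A11 (2.16±0.24), the myosin MYH15 (1.97±0.20), the zinc finger gene ZNF425 (1.87±0.17), C2orf16 (1.79±0.19), the aldehyde dehydrogenase ALDH8A1 (1.72±0.21) and AHNAK2 (1.39±0.16). SMAD6 (-1.44±0.16), LRATD2 (-1.22±0.11), LINC01605 (-1.12±0.20), FOXCUT (-1.03±0.14) and SNHG4 (-1.01±0.16) fell. In edgeR's test these genes had adjusted p from 5.3e-11 to 0.0021. Of the histone genes, 14 of 32 rose and 0 fell (19 and 0 over the list alone). The median was 1.21, also with members at their bound, with camera adjusted p = 3.9e-15 (2.9e-06 with an estimated correlation). The number risen was 9 and 6 without untreated WT replicate 1 or 2. Of the p53 targets, 5 of 28 rose and 0 fell (9 and 0 over the list alone; scaled 1 and 1, 0 and 0). The median was 0.14, 0.17 with members near the floor left out, with camera adjusted p = 0.0065 (0.038 with an estimated correlation). The median was -0.07 with mitochondrial scaling and -0.08 with the authors' factors. The number risen was 0 and 0 without untreated WT replicate 1 or 2, and 3 without treated WT replicate 2. Of the DNA replication genes, 0 of 31 rose and 1 fell (0 and 3 over the list alone; scaled 0 and 9, 0 and 1). The median was -0.08, with camera adjusted p = 0.0026 (0.038 with an estimated correlation). The number fallen was 0 and 0 without untreated WT replicate 1 or 2, and 2 without treated WT replicate 1. With the preset correlation camera further called upward the ATF4 targets and the ribosomal protein genes (signs turned by both scalings) and the mitochondrially encoded mRNAs, and downward the Integrator subunits, the snoRNA host genes, the G2 and mitosis genes, the splicing factors and the DNA damage response genes (adjusted p = 0.1 to 0.71 with an estimated correlation). The immune markers had a median of 1.53 (1 risen and 0 fallen of 3, camera adjusted p = 0.024). The kidney or neuronal markers had one of -0.26 (0 and 2 of 4, camera adjusted p = 0.0084), both 0.12 to 0.15 with an estimated correlation.

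In the WT line 985 genes were called by edgeR's test (618 risen and 367 fallen). The count was 2300 with mitochondrial scaling (406 higher and 1894 lower, median -0.17), 3569 with GC correction (1796 higher and 1773 lower) and 653 with the authors' factors (274 higher and 379 lower, median -0.19), and 50 when the line's own 4 libraries were fitted alone. It was 305 and 282 without untreated WT replicate 1 or 2, and 433 without treated WT replicate 2.

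The difference in change between the WT and the degron line was tested next. Only the treated WT libraries of this pair had doxycycline, so effects of the wild-type copy and of doxycycline cannot be told apart in this difference. MYC went from 257 to 185 CPM in WT and 519 to 23.1 CPM in the degron line, a difference of 4.02±0.19, and that of HSPA6 was 6.83±1.40. It was also above 0 for HES5 (5.05±0.50), NOG (3.22±0.36) and KCNJ11 (3.19±0.46), and below 0 for TPH1, a tryptophan hydroxylase (-2.49±0.40), the cone transducin GNAT2 (-2.21±0.40), PTAFR, a receptor for platelet-activating factor (-2.02±0.26), GPR179 (-2.00±0.40) and LRRC39 (-1.99±0.41). Of the short-lived mRNAs, 12 of 35 were higher and 0 lower (15 and 0 over the list alone; scaled 16 and 0, 26 and 0). The median was 0.80, with camera adjusted p = 3.4e-11, adjusted p = 0.088 with an estimated correlation. Of ATF4 targets, 11 of 24 were higher and 1 lower (the same over the list alone; scaled 12 and 0, 18 and 0). The median was 0.48, with camera adjusted p = 8.5e-07, adjusted p = 0.097 with an estimated correlation. At the preset correlation alone camera also called snoRNA host genes, NF-kB targets, mitochondrial mRNAs and respiratory chain genes (signs of both turned by both scalings) and BCL2 family (adjusted p = 0.088 to 0.43 with an estimated correlation). These genes had adjusted p from 1.0e-11 to 0.0026 in edgeR's test, which called a differing change for 2403 genes, 1646 higher and 757 lower. The count was 5803 with GC correction, 2872 with mitochondrial scaling (2653 higher and 219 lower, median 0.28) and 6173 with the authors' factors (6044 higher and 129 lower, median 0.63). It was 1504 without untreated degron replicate 1, and 1452 and 1445 without untreated WT replicate 1 or 2.

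In the Y1F line, MYC fell from 241 to 18.3 CPM (-3.72±0.15) and IRS4 from 1309 to 105 CPM (-3.63±0.13). LRATD2 (-3.32±0.12), KCNJ11 (-3.05±0.38), SMAD6 (-2.98±0.17), the rRNA methyltransferase MRM1 (-2.85±0.28), KAT5 (-2.57±0.22), DHRS2 (-2.56±0.24), the neurofilament subunit NEFM (-2.46±0.16) and the Mediator subunit MED11 (-2.41±0.16) also fell. Higher after treatment were the fucosyltransferases FUT6 (ratio 239, 42.6 to 9480.0 as counting interval) and FUT3 (5.15±0.30), ELAPOR1 (5.98±0.20), IQCN (5.45±0.35), albumin (ALB, 4.69±0.39), UNC79 (4.46±0.25), the germ cell gene TEX14 (4.36±0.19), CLIC5 (3.97±0.27), the kainate receptor subunit GRIK5 (3.86±0.29) and C1orf116 (3.85±0.27). With edgeR's test, adjusted p from 1.1e-14 to 2.1e-06 for these genes, calls were made for 8795 genes in all (4606 risen and 4189 fallen). The count was 9993 with mitochondrial scaling (2667 higher and 7326 lower, median -0.30) and 13592 with the authors' factors (1610 higher and 11982 lower, median -0.82). In Y1F, of the histone genes, 29 of 32 rose and 0 fell (the same over the list alone). The median was 2.12, with camera adjusted p = 5.3e-13 (7.9e-06 with an estimated correlation). Of the snoRNA host genes in Y1F, 1 of 18 rose and 11 fell (1 and 13 over the list alone). The median was -0.86, -0.92 with members near the floor left out, with camera adjusted p = 1.4e-04 (0.048 with an estimated correlation). Of p53 targets in Y1F, 12 of 28 rose and 4 fell (13 and 4 over the list alone; scaled 8 and 6, 2 and 12). The median was 0.42, 0.41 with members near the floor left out, with camera adjusted p = 0.0063 (0.024 with an estimated correlation). The median was -0.45 with the authors' factors. Of the heat shock genes in Y1F, 1 of 18 rose and 9 fell (1 and 11 over the list alone; scaled 0 and 15, 0 and 18). The median was -0.34, with camera adjusted p = 0.0013 (0.024 with an estimated correlation). Of the DNA replication genes in Y1F, 3 of 31 rose and 17 fell (4 and 18 over the list alone; scaled 1 and 23, 0 and 29). The median was -0.31, with camera adjusted p = 0.0025 (0.024 with an estimated correlation). At the preset correlation camera also called upward the mitochondrial mRNAs (sign turned by the authors' factors), and downward the splicing factors and the BCL2 family (adjusted p = 0.12 to 0.42 with an estimated correlation). The immune markers had a median of 2.92 (3 risen and 0 fallen of 3, camera adjusted p = 0.04). The endothelial markers had one of 3.38, also with members at their bound (3 and 0 of 4, camera adjusted p = 0.031). The kidney or neuronal markers had one of -1.28 (1 and 3 of 4, camera adjusted p = 0.024), all 0.095 to 0.12 with an estimated correlation.

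Set against WT, the change in Y1F was higher for GRIK5 (3.06±0.47), CRISPLD2 (3.04±0.22), TEX14 (2.45±0.29), the neuronal pentraxin NPTX2 (2.43±0.35) and the immediate early gene FOSB (2.40±0.27), and lower for MYC (-3.25±0.19), KCNJ11 (-2.74±0.49), IRS4 (-2.73±0.17) and TRIM47 (-2.70±0.40). Of the histone genes, in this difference, 7 of 32 were higher and 0 lower (11 and 0 over the list alone; scaled 3 and 0, 4 and 0). The median was 1.03, with camera adjusted p = 4.3e-06 (9.0e-04 with an estimated correlation). The number higher was 2 and 4 without untreated WT replicate 1 or 2, 3 without treated WT replicate 1, 2 and 4 without untreated Y1F replicate 1 or 2, and 3 and 3 without treated Y1F replicate 1 or 2. Of the heat shock genes, likewise, 0 of 18 were higher and 5 lower (0 and 6 over the list alone; scaled 0 and 5, 0 and 14). The median was -0.20, with camera adjusted p = 6.2e-05 (0.011 with an estimated correlation). The number lower was 3 without untreated WT replicate 1, 3 without treated WT replicate 2, 3 without untreated Y1F replicate 1, and 3 without treated Y1F replicate 1. At the preset correlation alone camera also called snoRNA host genes, p53 targets (sign turned by the authors' factors), ATF4 targets, ribosomal protein genes and splicing factors (adjusted p = 0.059 to 0.84 with an estimated correlation). In edgeR's test these genes had adjusted p from 1.5e-09 to 0.0011, and the change differed for 1944 genes, 684 higher and 1260 lower. The count was 5150 with GC correction, 1519 with mitochondrial scaling (292 higher and 1227 lower, median -0.14) and 7019 with the authors' factors (179 higher and 6840 lower, median -0.64). It was 1035 and 1022 without untreated WT replicate 1 or 2, 1161 without treated WT replicate 2, 1061 without untreated Y1F replicate 1, and 922 without treated Y1F replicate 1.

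In the S2A line, the Toll-like receptor adaptor MYD88 (5.74±0.26), the growth factor HBEGF (4.10±0.18), FOSB (4.02±0.19), the transcription factor SNAI1 (3.93±0.27), GRIK5 (4.30±0.27), the myosin light chain MYL11 (4.63±0.35), ELAPOR1 (3.90±0.20), TEX14 (3.61±0.16) and the poly(A) polymerase TENT5C (3.58±0.17) rose, and MGAM2 was higher (ratio 162, 44.3 to 1340.0 as counting interval). The retinaldehyde reductase DHRS3 fell from 17 to 3.19 CPM (-2.40±0.19) and IRS4 from 935 to 192 CPM (-2.28±0.12), with the Wnt receptor FZD8 (-2.25±0.27), PRR5 (-1.91±0.28), MED11 (-1.89±0.15), DEXI (-1.86±0.17), HNRNPDL (-1.83±0.13), BTN3A2 (-1.83±0.12) and DHRS2 (-1.82±0.25). These genes had adjusted p from 1.4e-12 to 1.9e-05 in edgeR's test, which called 7015 genes in all (3387 risen and 3628 fallen). The count was 10689 with mitochondrial scaling (1480 higher and 9209 lower, median -0.50) and 10144 with the authors' factors (1374 higher and 8770 lower, median -0.53). In S2A, of the histone genes, 28 of 32 rose and 0 fell (29 and 0 over the list alone). The median was 1.96, 1.85 with members at their bound, with camera adjusted p = 4.8e-15 (3.1e-06 with an estimated correlation). Of the short-lived mRNAs in S2A, 19 of 35 rose and 3 fell (20 and 3 over the list alone). The median was 0.98, with camera adjusted p = 1.3e-09, adjusted p = 0.11 with an estimated correlation. With the preset correlation camera further called upward the ribosomal protein genes and the mitochondrial mRNAs (signs turned by both scalings, adjusted p = 0.31 to 0.82 with an estimated correlation). The endothelial markers had a median of 2.62 (3 risen and 0 fallen of 4, camera adjusted p = 0.025), with adjusted p = 0.11 with an estimated correlation.

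Against WT, the change in S2A was higher for MYD88 (4.32±0.62), GRIK5 (3.50±0.46), HBEGF (3.45±0.25), FOSB (3.14±0.28) and the kinase SGK1 (3.00±0.17), and lower for SLC7A11 (-2.60±0.38), DHRS3 (-2.42±0.25) and SMIM10L2B (-1.92±0.36). Of the short-lived mRNAs, in S2A against WT, 13 of 35 were higher and 1 lower (15 and 2 over the list alone). The median was 0.67, with camera adjusted p = 3.0e-15 (0.038 with an estimated correlation). At the preset correlation alone camera also called histone genes, ATF4 targets, ribosomal protein genes and mitochondrial mRNAs (signs of the last 2 turned by both scalings, adjusted p = 0.063 to 0.96 with an estimated correlation). By edgeR's test, adjusted p from 7.0e-10 to 0.0026 for these genes, the change differed for 1505 genes, 574 higher and 931 lower. The count was 4749 with GC correction, 1409 with DESeq2 size factors (694 higher and 715 lower), 2230 with mitochondrial scaling (198 higher and 2032 lower, median -0.35) and 1488 with the authors' factors (139 higher and 1349 lower, median -0.36). It was 699 and 689 without untreated WT replicate 1 or 2, 660 and 704 without untreated S2A replicate 1 or 2, and 759 and 688 without treated S2A replicate 1 or 2.

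In the T4V line, MGAM2 (6.43±0.38), MGAM (3.27±0.22), PHF24 (3.10±0.18), the histone genes H2BC21 (3.00±0.18) and H2BC11 (2.26±0.18), TEX14 (2.69±0.19), ALDH8A1 (2.65±0.24), MYH15 (2.41±0.20), PLCL1 (2.33±0.25) and the arrestin-domain gene ARRDC3 (2.25±0.22) rose. The glycine transporter SLC6A9 fell from 9.04 to 1.63 CPM (-2.44±0.35), as did ZBTB12 (-2.57±0.27), MRM1 (-2.52±0.28), IRS4 (-2.41±0.12), the co-chaperone DNAJB12 (-2.06±0.16), the nucleoside transporter SLC29A2 (-2.04±0.24), FJX1 (-2.00±0.21) and LRATD2 (-1.98±0.12). In edgeR's test these genes had adjusted p from 5.5e-11 to 3.2e-05, and the calls were 5766 genes in all (2959 risen and 2807 fallen). The count was 8917 with GC correction, 2648 with its 4 libraries alone, 10476 with mitochondrial scaling (831 higher and 9645 lower, median -0.54) and 7618 with the authors' factors (888 higher and 6730 lower, median -0.41). It was 3504 and 3381 without treated T4V replicate 1 or 2. In T4V, of the histone genes, 27 of 32 rose and 0 fell (the same over the list alone). The median was 2.03, with camera adjusted p = 3.4e-18 (8.7e-07 with an estimated correlation). Of the snoRNA host genes in T4V, 1 of 18 rose and 11 fell (1 and 13 over the list alone). The median was -0.51, with camera adjusted p = 2.1e-04, adjusted p = 0.11 with an estimated correlation. Camera at the preset correlation also called upward the mitochondrial mRNAs (sign turned by mitochondrial scaling) and, with signs turned by both scalings, the RNAPII elongation factors, the immediate early and short-lived mRNAs, the ribosomal protein genes and the respiratory chain genes (adjusted p = 0.15 to 0.79 with an estimated correlation). The endothelial markers had a median of 2.71 and 2.33 with members at their bound (3 risen and 0 fallen of 4, camera adjusted p = 0.027) and the kidney or neuronal markers one of -0.63 (0 risen and 2 fallen of 4, camera adjusted p = 0.032), with adjusted p = 0.11 to 0.2 with an estimated correlation.

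Against WT, the change in T4V was higher for SAMD5 (1.72±0.30) and lower for SLC6A9 (-2.77±0.45), ZBTB12 (-2.19±0.37), MRM1 (-2.15±0.36) and SLC29A2 (-1.80±0.32). Of the histone genes, in T4V against WT, 3 of 32 were higher and 0 lower (the same over the list alone). The median was 0.57, with camera adjusted p = 3.4e-04 (0.0077 with an estimated correlation). At the preset correlation alone camera also called RNAPII elongation factors and mitochondrial mRNAs (signs turned by mitochondrial scaling), snoRNA host genes, ATF4 targets and G2 and mitosis genes (adjusted p = 0.095 to 0.44 with an estimated correlation). These genes had adjusted p from 0.0024 to 0.004 in edgeR's test, which called a differing change for 740 genes, 271 higher and 469 lower. The count was 3563 with GC correction, 1254 with the DESeq2 Wald test, 2147 with mitochondrial scaling (26 higher and 2121 lower, median -0.39) and 588 with the authors' factors (12 higher and 576 lower, median -0.24). It was 244 and 149 without untreated WT replicate 1 or 2, 1721 and 231 without treated WT replicate 1 or 2, 228 and 1502 without untreated T4V replicate 1 or 2, and 187 and 182 without treated T4V replicate 1 or 2.

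In the S5A line, MYC fell from 254 to 13.9 CPM (-4.19±0.15) and IRS4 from 915 to 52.8 CPM (-4.12±0.13), with LRATD2 (-3.80±0.13), the transcription factor SNAI2 (-3.48±0.17), FJX1 (-3.43±0.24), the secreted ligand WNT10B (-3.09±0.26), SMAD6 (-3.08±0.17), FZD8 (-2.91±0.28) and KCNJ11 (-2.89±0.40). The prostaglandin receptor PTGER3 (6.29±0.38), FUT3 (6.13±0.28), the muscle repair gene TRIM72 (5.73±0.45), SELPLG (5.06±0.46), the spectrin SPTBN5 (4.88±0.36) and SBSN (4.81±0.40) rose, and TG (ratio 190.0, 64.6 to 924) and CDHR4 (ratio 336, 59.8 to 13300.0, both as counting intervals) were higher. With edgeR's test, adjusted p from 7.2e-15 to 4.1e-06 for these genes, calls were made for 9928 genes in all (5098 risen and 4830 fallen). The count was 13480 with mitochondrial scaling (2121 higher and 11359 lower, median -0.70) and 14245 with the authors' factors (1749 higher and 12496 lower, median -0.92). Of the Integrator subunits in S5A, 0 of 14 rose and 10 fell (0 and 11 over the list alone). The median was -0.47, with camera adjusted p = 6.5e-04 (0.013 with an estimated correlation). In S5A, of the histone genes, 31 of 32 rose and 0 fell (the same over the list alone). The median was 2.43, with camera adjusted p = 3.5e-15 (1.3e-05 with an estimated correlation). Of the heat shock genes in S5A, 2 of 18 rose and 12 fell (2 and 13 over the list alone). The median was -0.48, with camera adjusted p = 5.6e-04 (0.016 with an estimated correlation). Of the DNA replication genes in S5A, 2 of 31 rose and 16 fell (the same over the list alone; scaled 0 and 29, 0 and 29). The median was -0.34, with camera adjusted p = 0.0014 (0.019 with an estimated correlation). With the preset correlation camera further called upward the p53 targets (sign turned by both scalings) and the mitochondrial mRNAs (sign turned by the authors' factors), and downward the ATF4 targets, the G2 and mitosis genes, the splicing factors and the DNA damage response genes (adjusted p = 0.067 to 0.31 with an estimated correlation). The immune markers had a median of 4.04 and 2.18 with members at their bound (3 risen and 0 fallen of 3, camera adjusted p = 0.021). The kidney or neuronal markers had one of -1.08 (1 and 3 of 4, camera adjusted p = 0.024), both 0.09 to 0.18 with an estimated correlation.

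Against WT, the change in S5A was lower for MYC (-3.72±0.20), IRS4 (-3.21±0.17), SLC6A9 (-3.18±0.43) and SLC7A11 (-3.16±0.38), and higher for FUT3 (3.89±0.59), PHLDA1 (2.53±0.32) and IFITM10 (2.53±0.46). Of the Integrator subunits, in S5A against WT, 0 of 14 were higher and 4 lower (0 and 6 over the list alone; scaled 0 and 11, 0 and 14). The median was -0.33, with camera adjusted p = 0.002 (0.017 with an estimated correlation). Of the histone genes, in S5A against WT, 10 of 32 were higher and 0 lower (the same over the list alone; scaled 5 and 0, 5 and 1). The median was 1.10, with camera adjusted p = 1.4e-06 (5.8e-04 with an estimated correlation). The number higher was 6 without untreated WT replicate 1, and 6 without treated S5A replicate 2. Of the heat shock genes, in S5A against WT, 1 of 18 were higher and 7 lower (1 and 8 over the list alone; scaled 0 and 16, 0 and 16). The median was -0.37, with camera adjusted p = 1.2e-05 (0.006 with an estimated correlation). Camera's further calls at the preset correlation alone were ATF4 targets, DNA replication genes, G2 and mitosis genes, mitochondrial mRNAs (sign turned by both scalings) and DNA damage response genes (adjusted p = 0.065 to 0.38 with an estimated correlation). In edgeR's test these genes had adjusted p from 1.1e-10 to 6.6e-04, and the change differed for 3613 genes, 1279 higher and 2334 lower. The count was 6767 with GC correction, 7327 with mitochondrial scaling (375 higher and 6952 lower, median -0.55) and 8717 with the authors' factors (281 higher and 8436 lower, median -0.74). It was 2315 without untreated WT replicate 2, and 2373 without treated S5A replicate 2.

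In the S7A line, HSPA6 rose from 0.138 to 55.9 CPM (8.60±0.37), with WFIKKN2 (5.46±0.38), the protease CORIN (4.87±0.28), MOBP (4.69±0.29), ELAPOR1 (4.50±0.19) and the galanin receptor GALR2 (4.16±0.30), and MGAM2 was higher (ratio 379, 67.6 to 15000.0 as counting interval). IRS4 fell from 1109 to 262 CPM (-2.08±0.12), with LRATD2 (-2.05±0.12), the tRNA methyltransferase TRDMT1 (-1.94±0.27), MED11 (-1.84±0.15), CHIC1 (-1.83±0.27), ARRDC4 (-1.79±0.16), TRIQK (-1.78±0.31), SNAI2 (-1.67±0.14), ZNF239 (-1.67±0.19) and the homeobox gene ALX1 (-1.67±0.17). These genes had adjusted p from 1.4e-12 to 1.6e-04 in edgeR's test, which called 6967 genes in all (3547 risen and 3420 fallen). The count was 3458 with its 4 libraries alone, 9498 with mitochondrial scaling (1853 higher and 7645 lower, median -0.38) and 13564 with the authors' factors (1297 higher and 12267 lower, median -0.81). It was 4290 without untreated S7A replicate 1. In S7A, of the histone genes, 23 of 32 rose and 0 fell (the same over the list alone; scaled 19 and 0, 15 and 0). The median was 1.5, with camera adjusted p = 2.8e-10 (3.4e-05 with an estimated correlation). Of the DNA damage response genes in S7A, 0 of 18 rose and 9 fell (0 and 10 over the list alone; scaled 0 and 14, 0 and 18). The median was -0.40, with camera adjusted p = 0.001, adjusted p = 0.24 with an estimated correlation. At the preset correlation camera also called upward the mitochondrial mRNAs (sign turned by the authors' factors), and downward the Integrator subunits, the snoRNA host genes, the HIF targets, the G2 and mitosis genes and the splicing factors (adjusted p = 0.059 to 0.24 with an estimated correlation). The immune markers had a median of 3.68 (3 risen and 0 fallen of 3, camera adjusted p = 0.0042). The endothelial markers had one of 3.34 and 2.94 with members at their bound (2 and 0 of 4, camera adjusted p = 0.029), both 0.059 to 0.11 with an estimated correlation.

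Against WT, the change in S7A was higher for CALCB, a calcitonin gene-related peptide (3.27±0.20), ADAMTSL4 (2.13±0.35), KRBA2 (1.83±0.24) and RGS16, a regulator of G protein signalling (1.56±0.23), and lower for MED11 (-1.26±0.20), and camera called no list. By edgeR's test, adjusted p from 4.4e-09 to 0.007 for these genes, the change differed for 164 genes, 65 higher and 99 lower. The count was 2458 with GC correction, 373 with the DESeq2 Wald test, 133 with DESeq2 size factors (81 higher and 52 lower), 222 with mitochondrial scaling (27 higher and 195 lower, median -0.22) and 4367 with the authors' factors (69 higher and 4298 lower, median -0.63). It was 19 and 29 without untreated WT replicate 1 or 2, 22 and 101 without untreated S7A replicate 1 or 2, and 55 without treated S7A replicate 2. It was 105 without Mock.

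The genes that moved at least 2-fold in degron were followed in the other lines. The 2453 that rose there had a median of 2.23, and of 0.98 in WT, 2.02 in Y1F, 1.48 in S2A, 1.30 in T4V, 2.19 in S5A and 1.88 in S7A (with the authors' factors 1.39 in degron, 0.75, 1.17, 0.98, 0.86, 1.25 and 1.07 in the same order). The 1642 that fell there had a median of -1.39, and of -0.29 in WT, -1.01 in Y1F, -0.79 in S2A, -0.65 in T4V, -1.14 in S5A and -0.80 in S7A (with the authors' factors -2.24 in degron, -0.53, -1.88, -1.31, -1.11, -2.09 and -1.62). These genes were picked on the degron libraries, so their size in that line is not independent evidence. Across 11654 genes with a mean of at least 5 CPM, which are not independent replicates, the log2 fold changes of 2 lines correlated with Pearson's r from 0.513 (WT and T4V) to 0.832 (degron with Y1F, and Y1F with S5A), with 0.792 for WT and S7A. With GC correction it ran from 0.564 (WT and S2A) to 0.835 (S5A and S7A), with 0.617 for WT and T4V and 0.776 for WT and S7A. In the authors' deposited table, the log2 fold change of MYC was -5.35 in the degron line, -0.68 in WT, -4.59 in Y1F, -1.35 in S2A, -2.06 in T4V, -5.14 in S5A and -2.41 in S7A, and that of HSPA6 was -1.11, 6.40, 2.78, 2.78, 2.86, 1.45 and 7.84 in the same order.

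**Figure D3:**
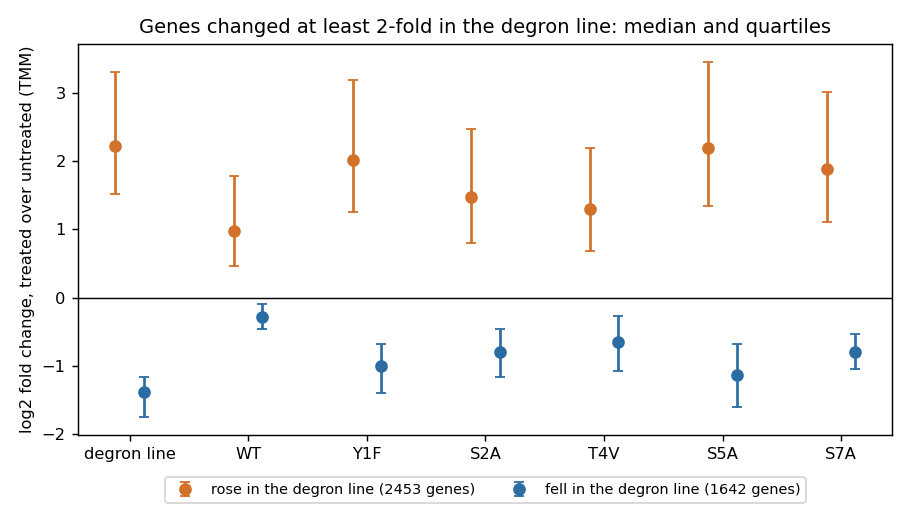
Median log2 fold change (points) with quartiles (bars) of treated over untreated libraries, for the 2453 genes that rose and the 1642 that fell at least 2-fold in the degron line, in each of the 7 lines with TMM. In WT the medians were 0.98 and -0.29.

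**Figure D4:**
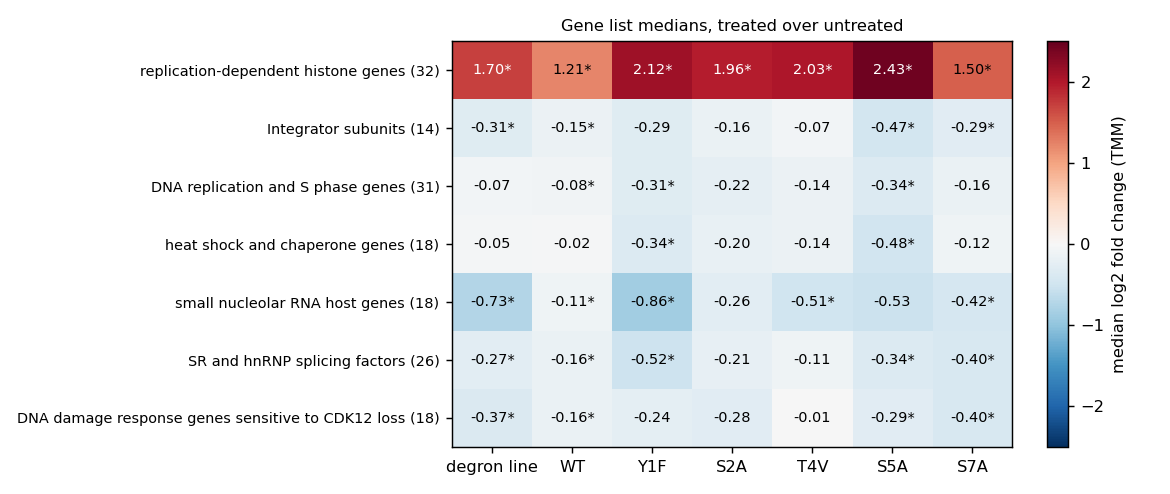
Median log2 fold change, treated over untreated with TMM, of 7 gene lists (numbers of genes in parentheses) in each of the 7 lines, with an asterisk where camera with the preset correlation gave an adjusted p under 0.05. The histone genes had medians from 1.21 in WT to 2.43 in S5A.

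Before treatment, the degron line differed from Mock for 12955 genes in edgeR's test (6671 higher and 6284 lower). AKR1B10 (at least 50600.0-fold), AKR1C3 (at least 23700.0-fold) and AKR1C1 (at least 14700.0-fold), aldo-keto reductases, the drug transporter ABCC3 (at least 6300.0-fold) and the adhesion protein CEACAM6 (at least 5190.0-fold) were lower in the degron line. SLIT2, a guidance ligand (at least 1460.0-fold), the cell cycle inhibitor CDKN2A (at least 879-fold), the laminin LAMA1 (at least 796-fold) and the cyclin CCND2 (at least 795-fold) were higher there, as was IRS4 (ratio 14300.0, 3960.0 to 118000.0 as counting interval). Of the NRF2 targets, 0 of 28 were higher and 28 lower (the same over the list alone). The median was -4.34, also with members at their bound, with camera adjusted p = 9.7e-24 (3.1e-05 with an estimated correlation). Of the A549 and lung epithelial genes, 2 of 16 were higher and 11 lower (the same over the list alone). The median was -4.17, also with members at their bound, with camera adjusted p = 2.1e-06 (0.0054 with an estimated correlation). Of the NF-kB targets, likewise, 0 of 14 were higher and 12 lower (the same over the list alone). The median was -4.71, -4.67 with members at their bound, with camera adjusted p = 2.1e-06 (0.032 with an estimated correlation). Of the histone genes, against Mock, 3 of 32 were higher and 17 lower (the same over the list alone). The median was -1.31, also with members at their bound, with camera adjusted p = 0.022 (0.042 with an estimated correlation). Camera made no call with GC correction (adjusted p = 0.057). Of the p53 targets, against Mock, 5 of 28 were higher and 17 lower (6 and 17 over the list alone). The median was -0.99, with camera adjusted p = 0.0096 (0.032 with an estimated correlation). Of the heat shock genes, against Mock, 3 of 18 were higher and 15 lower (the same over the list alone; 5 and 8 with mitochondrial scaling). The median was -0.84, with camera adjusted p = 0.0078 (0.045 with an estimated correlation). Camera made no call with mitochondrial scaling (adjusted p = 0.074). Camera with the preset correlation also called upward the ribosomal protein genes, and downward the short-lived mRNAs and the mitochondrial mRNAs (sign turned by mitochondrial scaling) (adjusted p = 0.59 to 0.8 with an estimated correlation). The fibroblast markers had a median of 5.47 (3 risen and 0 fallen of 3, camera adjusted p = 0.022), with adjusted p = 0.061 with an estimated correlation. The single genes had adjusted p from 3.5e-21 to 2.8e-09 in edgeR's test, and the count was 13549 with mitochondrial scaling (9890 higher and 3659 lower, median 0.64).

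The untreated lines were also compared with the untreated degron line, by edgeR's test. The level in WT was higher for LINC01963 (1.35±0.15), ZC3H12C (1.23±0.21) and LGR5 (1.21±0.16) and lower for C3orf18 (-4.03±0.35), UNCX (-3.60±0.36) and PTH1R (-2.17±0.25), among 2038 called (765 higher and 1273 lower, adjusted p from 4.6e-07 to 7.0e-04 for those named). The count was 5070 with GC correction and 2166 with mitochondrial scaling (1645 higher and 521 lower, median 0.14). It was 611 and 1320 without untreated degron replicate 1 or 2, and 716 and 629 without untreated WT replicate 1 or 2. In Y1F it was higher for BARX2 (1.29±0.18) and SEMA3C (1.21±0.17) and lower for SLC6A11 (ratio 312, 55.6 to 12400.0), among 2207 called (861 higher and 1346 lower, adjusted p from 6.6e-11 to 1.7e-04 for those named). The count was 5306 with GC correction and 1388 with mitochondrial scaling (667 higher and 721 lower). It was 749 and 1353 without untreated degron replicate 1 or 2, and 1337 and 790 without untreated Y1F replicate 1 or 2. In S2A it was higher for NAP1L3 (ratio 308, 54.8 to 12200.0), ZNF675 (6.17±0.42) and TMEM178B (4.67±0.28) and lower for PPP1R14A (ratio 363, 64.8 to 14400.0), UNCX (-7.52±0.56) and FENDRR (-6.36±0.28), among 7249 called (3662 higher and 3587 lower, adjusted p from 1.1e-12 to 3.6e-08 for those named). In T4V it was higher for MAGEA6 (4.54±0.20) and LINC01963 (1.80±0.15) and lower for IQSEC3 (-2.29±0.26) and NGFR (-2.08±0.27), among 2655 called (1137 higher and 1518 lower, adjusted p from 1.1e-08 to 3.9e-05 for those named). The count was 6139 with GC correction and 3312 with mitochondrial scaling (2663 higher and 649 lower, median 0.20). It was 1115 and 1567 without untreated degron replicate 1 or 2, and 1609 without untreated T4V replicate 2. In S5A it was higher for ATF5 (1.33±0.20) and CCNE2 (1.29±0.21) and lower for CACNA1G (-1.97±0.29), among 2546 called (1152 higher and 1394 lower, adjusted p from 1.1e-04 to 2.9e-04 for those named). The count was 5786 with GC correction and 5368 with mitochondrial scaling (4894 higher and 474 lower, median 0.31). It was 959 without untreated degron replicate 1, and 974 and 1264 without untreated S5A replicate 1 or 2. In S7A it was higher for EMILIN2 (2.13±0.12) and GNAO1 (1.89±0.25) and lower for TRO (-3.07±0.19) and IMPACT (-2.61±0.19), among 3738 called (1682 higher and 2056 lower, adjusted p from 2.9e-10 to 1.9e-05 for those named). The count was 7290 with GC correction and 4872 with mitochondrial scaling (3912 higher and 960 lower, median 0.23). It was 1953 without untreated degron replicate 1, and 2121 and 2322 without untreated S7A replicate 1 or 2.

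Of the 20 HIF targets tested, 6 were lower in WT (6 over the list alone, 2 without untreated degron replicate 1, 3 without untreated WT replicate 2), 7 in Y1F (10 over the list alone, 2 without untreated degron replicate 1, 4 without untreated Y1F replicate 2), 11 in S2A (13 over the list alone), 7 in T4V (9 over the list alone, 3 without untreated degron replicate 1, 3 without untreated T4V replicate 2), 9 in S5A (11 over the list alone, 4 without untreated degron replicate 1, 4 and 4 without untreated S5A replicate 1 or 2) and 9 in S7A (11 over the list alone, 4 without untreated degron replicate 1). Their medians were -0.28 to -0.45, and camera called them in each (adjusted p = 4.5e-06 to 3.9e-04, and adjusted p = 0.0017 to 0.02 with an estimated correlation). These 6 comparisons share the 2 untreated degron libraries, so their agreement is not independent evidence. With either correlation camera also called the heat shock genes upward in WT, Y1F, T4V and S5A (medians 0.17 to 0.31), the kidney or neuronal markers downward in Y1F, T4V and S7A (medians -0.99 to -0.68), the cleavage, polyadenylation and termination factors upward in Y1F, S2A, T4V, S5A and S7A (medians 0.15 to 0.31, lost with GC correction in the last 3), the Integrator subunits upward in S2A and S5A (medians 0.22 to 0.33), the histone genes upward in S2A, T4V and S5A (medians 0.45 to 0.85, lost with mitochondrial scaling in the last 2), the cholesterol synthesis genes downward in S2A (median -0.51), the DNA replication genes upward in T4V, S5A and S7A (medians 0.13 to 0.29), the cholesterol synthesis genes upward in T4V (median 0.25) and the fibroblast markers downward in S5A (median -1.20), with adjusted p = 0.0017 to 0.048 with an estimated correlation.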

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

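Except for the tests of differences between lines and the shares of genes near an expressed neighbour and of genes at 0 that gained counts, the tests given here were chosen only after their results were seen. The change with treatment differed between lines, by the test of the difference itself, for 2403 genes in WT against the degron line, and against WT for 1944 genes in Y1F, 1505 in S2A, 740 in T4V, 3613 in S5A and 164 in S7A. With GC correction these were 5803, 5150, 4749, 3563, 6767 and 2458, and with 1 library left out as few as 1445, 922, 660, 149, 2315 and 19. Among the lists camera called the difference at either correlation for the histone genes in Y1F (median 1.03), T4V (0.57) and S5A (1.10), the heat shock and chaperone genes in Y1F (-0.20) and S5A (-0.37), the short-lived mRNAs in S2A (0.67) and the Integrator subunits in S5A (-0.33).

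Replicates of a group differed along transcript GC content. A length curve removed a median of 0.528% of the variance left after GC, which argues against transcript length as the common source over the 15 groups, though it removed 13.5% in untreated S7A. A GC curve fitted on the even-numbered chromosomes removed a median of 39.2% of the variance of the replicate difference on the other chromosomes (0.546% in treated S5A to 75.8% in treated S7A), so GC bias between libraries may account for part of the spread. Neither library preparation nor cells could be separated as its source.

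The 28 libraries of the degron and complemented lines lacked genes abundant in Mock: 39 genes had at least 100 CPM of the library total in both Mock libraries and under 1 CPM in all 28. Other cells mixed into Mock were argued against, since 26 genes with at least 20 CPM in all 28 lay under 0.1 CPM in both Mock libraries. CDKN2A and CDKN2B had 0 counts in both Mock libraries and MTAP 4 and 5, while their neighbours KLHL9 (833 and 792) and MLLT3 (493 and 478) were counted there, and all 28 others had at least 50 counts of the first 3, genes chosen after their values were seen; so cells of another line than Mock are a candidate explanation. A clone of the Mock cells with switched expression stays open. Its test looked at no neighbouring genes but these 3, all of which showed this, so it could not argue against a clone. By the kidney HEK293 or neuronal markers, NEFL (3.96 CPM in Mock, median 37.2 in the 28) and NEFM (0.192 and 49.6) were higher in the 28 but TUBB3 (6.84 and 0.42) and ENO2 (80.8 and 24.1, also a HIF target) lower, so they do not single out HEK293 as a candidate source, and the labels give A549 for all 30.

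Genes near 0 in the untreated degron line rose after treatment (1659 of 4666 tested genes under 1 CPM rose at least 2-fold). An even background of reads was argued against by 18.1% of protein-coding genes at 0 before treatment (664 of 3671) with a count in both treated libraries, and by CPM added per kb that differed 15.4-fold between the 90th and 10th percentile. Reads running on from an upstream gene may contribute: 23.9% of genes that rose had an expressed gene ending within 20 kb upstream on the same strand against 16.6% of those not called (ratio 1.44, two-sided Fisher's exact p = 3.3e-09; 1.15 for the other strand), too small a ratio to decide. Scaling by total counts after a loss of mRNA stays open: with the authors' factors 1018 of the 4666 were called upward and 567 downward, with a median of 0.11 (0.95 with TMM) against -0.91 in the other genes, but the genes were picked on these untreated libraries. A response of these genes to loss of RPB1 stays open and was not tested.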

How the results depend on the processing

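The settings with GC correction, the authors' factors and the fit without Mock were chosen only after the data were seen. The human to fly read ratio, the choice of fly reads and TMM beside a fly scaling were not run, since the tables hold 0 fly genes. Across the settings run for each and every left-out library, 7514 values of single genes stayed on their side of the threshold with the same sign, 501 lost the call, 19 gained one and 45 turned; for counts of called list members 1629 stayed within 1.5 times, 570 moved beyond and 27 turned; for camera, run only with DESeq2 size factors, the 2 scalings and GC correction, 484 kept the call, 76 lost it and 5 turned; and for counts of called genes 182 stayed within 1.5 times and 113 did not. DESeq2 size factors moved 0 of 20 counts of genes beyond 1.5 times. In simulated WT counts (19982 genes), 23.9% of 1.5-fold, 73.1% of 2-fold and 90.9% of 4-fold changes were called. Of 129 calls 4 (3.1%) were false. Small changes were often missed. Real WT replicates differ along GC content, so these shares may not hold for them.

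The counts of called genes that moved beyond 1.5 times were, with a mean CPM of at least 5, which tests fewer genes, 5670 in degron, 653 in WT, 5370 in Y1F, 6132 in S5A, 4237 in S7A and 8404 in untreated degron against Mock; with no low-count filter, 108 in S7A against WT; with the DESeq2 Wald test, 1254 in T4V against WT and 373 in S7A against WT; with each line's 4 libraries alone, 50 in WT, 2648 in T4V and 3458 in S7A; with the treated libraries compared directly, which adds the differences before treatment, 6765 in WT against degron, 5781 in Y1F against WT, 7975 in S2A against WT, 4041 in T4V against WT, 8058 in S5A against WT and 5092 in S7A against WT; without Mock, 105 in S7A against WT; and with GC correction, 3569 in WT, 8917 in T4V, 5803 in WT against degron, 5150 in Y1F against WT, 4749 in S2A against WT, 3563 in T4V against WT, 6767 in S5A against WT, 2458 in S7A against WT, 5070 in untreated WT against degron, 5306 in untreated Y1F against degron, 6139 in untreated T4V against degron, 5786 in untreated S5A against degron and 7290 in untreated S7A against degron. With mitochondrial scaling they were 2300 in WT, 10689 in S2A, 10476 in T4V, 2147 in T4V against WT, 7327 in S5A against WT, 1388 in untreated Y1F against degron and 5368 in untreated S5A against degron, and with the authors' factors 13543 in degron, 653 in WT, 13592 in Y1F, 13564 in S7A, 6173 in WT against degron, 7019 in Y1F against WT, 8717 in S5A against WT and 4367 in S7A against WT. Beyond what each setting changes by construction, the cause was not tested.

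The labels number the libraries of each group 1 and 2. The replicate difference of the treated libraries correlated across 11654 genes with that of the untreated ones at -0.74 in degron, -0.487 in WT, -0.604 in Y1F, 0.109 in S2A, -0.087 in T4V, 0.003 in S5A and 0.64 in S7A, so the numbers were not taken to pair libraries. With a replicate block over 28 libraries the counts that moved were 381 in WT, 1346 in WT against degron, 876 in Y1F against WT, 474 in S2A against WT, 58 in T4V against WT, 2289 in S5A against WT and 6 in S7A against WT, and with the block and GC correction 3321 in WT, 5348 in WT against degron, 4789 in Y1F against WT, 4381 in S2A against WT, 3165 in T4V against WT, 6375 in S5A against WT and 1939 in S7A against WT.

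With the authors' factors the sign turned for POLR2A -0.31, MT-ND2 -0.070, MT-CYB -0.19, NDUFA2 -0.099 in degron, POLR2A -0.75, MT-ND6 -0.017 in S5A against WT, POLR2A -0.60 in S7A against WT, MT-ND2 -0.21, MT-ND3 -0.32 in Y1F, RPS3A -0.11, RPL15 -0.12 in S2A, RPS3A -0.067, RPL5 -0.099, ATP5F1B -0.001 in T4V, MT-CYB -0.017 in S5A, MT-ND2 -0.22, MT-ND6 -0.24 in S7A and SDHC 0.11, UQCRB 0.22 in WT against degron. In lists that camera called, the called members turned from mostly one way to mostly the other, given with the number left the first way, for mitochondrial mRNAs risen (0 in degron, Y1F, S5A, S7A), respiratory chain genes risen (0 in degron, T4V), p53 targets risen (2 in Y1F, S5A, 1 in Y1F against WT), ribosomal protein genes risen (0 in S2A, T4V), elongation factors risen (0 in T4V), short-lived mRNAs risen (4 in T4V) and respiratory chain genes fallen (0 in WT against degron), and camera's direction turned (adjusted p = 0.96 for mitochondrial mRNAs in Y1F and 0.66 for ribosomal protein genes in T4V). With mitochondrial scaling the sign turned for POLR2A -0.032, RPS3A -0.18, RPL5 -0.23, SDHA -0.043, ATP5F1B -0.14 in T4V, POLR2A -0.50 in S5A against WT, POLR2A -0.10 in S7A against WT, POLR2A 0.34 in untreated degron against Mock, POLR2A 0.13 in untreated T4V against degron and RPS3A -0.091, RPL15 -0.096 in S2A, the called members for respiratory chain genes risen (0 in degron, T4V), ribosomal protein genes risen (0 in S2A, T4V), elongation factors risen (1 in T4V, 0 in T4V against WT), short-lived mRNAs risen (4 in T4V), p53 targets risen (3 in S5A), mitochondrial mRNAs risen (0 in S7A), G2 and mitosis genes risen (0 in T4V against WT), mitochondrial mRNAs fallen (0 in untreated T4V against degron), short-lived mRNAs fallen (2 in untreated S5A against degron) and ribosomal protein genes fallen (0 in untreated S5A against degron), and camera's direction (adjusted p = 0.98 for elongation factors in T4V, 0.19 for ribosomal protein genes in T4V and 0.64 for respiratory chain genes in T4V). With the treated libraries compared directly, CENPF in T4V against WT was -0.046. Both scalings shift all genes of a library by a single factor.

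With each library left out in turn, where a lone library is assumed to vary like those of the other groups, the counts of called genes ran from 282 to 1038 in WT, 3381 to 5545 in T4V, 4290 to 6737 in S7A, 1445 to 2793 in WT against degron, 922 to 2625 in Y1F against WT, 660 to 1792 in S2A against WT, 149 to 1721 in T4V against WT, 2315 to 4331 in S5A against WT, 19 to 129 in S7A against WT, 611 to 1320 in untreated WT against degron, 749 to 1353 in untreated Y1F against degron, 1115 to 2618 in untreated T4V against degron, 959 to 1742 in untreated S5A against degron and 1953 to 2508 in untreated S7A against degron. Those of POLR2A that turned sign, none of them called, ran from -0.83 to 0.15 in Y1F against WT, -0.68 to 0.30 in S2A against WT, -0.37 to 0.61 in S5A against WT, -0.33 to 0.65 in S7A against WT, -0.59 to 0.081 in untreated degron against Mock, -0.64 to 0.033 in untreated WT against degron, -0.50 to 0.18 in untreated Y1F against degron, -0.64 to 0.032 in untreated S2A against degron, -0.39 to 0.30 in untreated T4V against degron and -0.24 to 0.44 in untreated S5A against degron.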

Other observations

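The fits with the authors' factors given here were chosen only after the data were seen. The degron line had 4609 genes risen and 4272 fallen. Of these, 550 and 333 were called the same way in WT, 2042 and 1848 in T4V and 2275 and 2382 in S2A. The numbers were 2774 and 2612 in S7A, 3219 and 3045 in Y1F and 3358 and 3072 in S5A. The lines share no library but share a fit with pooled spread, so overlap by chance was not estimated. Opposite calls numbered 13 in WT, 57 in Y1F, 156 in S2A, 131 in T4V, 120 in S5A and 18 in S7A.

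Which scaling gives the amount of mRNA per cell is open. A hypothesis is that the authors' factors come from the fly RNA, of which 10% was added per the labels; they may then measure a loss of mRNA, since total counts over the factor were lower in both treated libraries than in both untreated ones in all lines but WT, where they overlapped, and the count of calls in the degron line was 13543 with them against 8881 with TMM. The fly reads were not analysed here, so this was not tested.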
